A study of Homo sapiens with 6 samples.

How the data were processed

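Total RNA of SH-SY5Y/TrkA cells was measured on a human Affymetrix oligonucleotide array with 54675 probe sets, 3 arrays of cells infected with EGFP alone and 3 of cells infected with dnEgr and EGFP. Groups and replicate numbers were taken from the sample descriptions. The deposited values are intensities on a linear scale, all above 0. The mean of each array after leaving out 2% of the values at each end was 150.02 in all 6 arrays, so the deposited intensities had been scaled to a common trimmed mean. The software that summarised probes into probe sets, and any background step, are not given in the sources used here. Detection calls were not used here, so the level of background is unknown and dim values may hold mostly background. A scaling to a common mean cannot show a change in total RNA per cell.

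Values were used as deposited and turned into log2(intensity + 16). A fold change on this scale understates the change of dim probe sets. The 62 control probe sets were left out, and so were probe sets whose mean log2 value over all 6 arrays lay under the 40th percentile, which left 32768. Gene symbols came from the platform's annotation and were matched by gene identifier to the RefSeq gene table of assembly GRCh38.p14, which was used for names alone. Of 54613 probe sets that were not controls, 41091 had 1 gene symbol, 1801 several and 11721 none. Over all 54675 probe sets the identifier match kept 41043 symbols, altered 0 and found no entry for 54, which kept their annotated symbol. A probe set with several symbols or none was tested but not named, which applied to 6640 tested probe sets. No coordinates are given because the files name no genome build. A gene was represented by its brightest tested probe set with 1 symbol, giving 13485 genes. Of these, 6841 had several tested probe sets, and in 4321 these disagreed in direction.

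Groups were compared with limma (lmFit, then eBayes with a mean-variance trend; limma 3.58.1, R 4.3.3), two-sided, on all 6 arrays with no covariate, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The median residual SD was 0.279 on the log2 scale, and 0.194 in genes above the 75th percentile of mean log2 intensity. Intervals are 95% confidence intervals from the same fit. Intensities are given as mean ± SD over 3 arrays. Means of intensity and of logarithms can differ in order. The 23 gene lists were fixed before the data were examined. They covered the Egr family and Nab co-repressors, other immediate early genes, Egr targets reported in other cells, MAP kinase feedback regulators, delayed NGF-response genes, neurite and cytoskeleton genes, axon guidance, noradrenergic identity, neurotrophin and GDNF signalling, synaptic release, cell cycle, p53 targets, apoptosis, interferon, NF-kappaB, unfolded protein, heat shock, cholesterol, glycolysis and hypoxia, TGF-beta and BMP, and markers of 3 other sources of cells. List members with no probe set of that symbol alone, or with all such probe sets under the filter, were not tested. A list result thus covers its tested members only. Lists with at least 5 tested members, 22 of them, were tested with camera at a preset correlation of 0.01 between genes and adjusted over the lists. Camera asks whether a list lies above or below the other genes. Camera with an estimated correlation, and fry, which asks whether the genes of a list move on balance one way, were alternatives.

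The genes named in the results were set by rule before the data were examined. They were all tested Egr and Nab genes, the 10 genes with the largest rise and the 10 with the largest fall among genes past the threshold whose groups did not overlap, and up to 4 members per list with the smallest p. How many of these were named in each list was chosen after the data were seen. No gene met the second part of the rule. Differences between 3′ and 5′ control probe sets were compared with an exact permutation test, two-sided.

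The fit was tested on simulated data with the real means and spread of the 32768 probe sets, with 200 probe sets changed in each of 20 simulations. It recovered 6.4% of probe sets changed 1.5-fold, 33% of those changed 2-fold, 75.9% at 3-fold and 87.3% at 4-fold, with a median of 9 false calls. A list of 21 genes shifted by 0.3 on the log2 scale was called by camera in 18 of 20 simulations over 13485 genes, with genes simulated as independent.

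Alternatives were pseudocounts of 1 and 64, no filter or a filter at the 60th percentile, quantile normalization, median centring, eBayes without trend or robust, array weights, the replicate number as a block, a fold of at least 1.5, the mean of a gene's probe sets, and leaving out each array in turn. Scaling to the spike-in RNAs and leaving out both arrays numbered 3 were added after the data were seen. The mean amount of that scaling was also added alone to all dnEgr values before camera. Counts, lists and named genes were recomputed where an alternative applied to them. The fold of at least 1.5 applied to the count of probe sets, the mean of a gene's probe sets to genes and lists, and the other list tests to lists. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.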

Results

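RNA was measured in SH-SY5Y/TrkA cells, a human neuroblastoma line with sympathetic neuron-like properties that carries TrkA, the receptor for nerve growth factor (NGF). The cells were infected 18 h before NGF was added and were harvested 3 h after it. They received either enhanced green fluorescent protein (EGFP) alone, the control, or EGFP together with dnEgr, a dominant negative form of Egr. Egr proteins are zinc finger transcription factors whose genes are switched on rapidly by growth factors, and a dominant negative form is meant to block their action on target genes. The comparison therefore asked which transcripts at 3 h of NGF depended on Egr activity. Expression of dnEgr and the block of Egr action were not checked here. The absence of a difference thus would not show that a transcript is independent of Egr. Each group had 3 arrays, numbered 1 to 3, and each array carried 54675 probe sets. The number of arrays limits the precision, and the labels do not say whether the arrays came from separate cultures, so p-values measure only the spread between these samples. Median intensity was 39.0, 34.4 and 33.3 on control arrays 1 to 3, and 38.3, 35.6 and 35.5 on dnEgr arrays 1 to 3. Cells without NGF were not analysed here, so the values describe the state after NGF and not the NGF response itself.

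No gene differed between dnEgr and control cells by more than the spread between arrays allowed. Of 13485 genes tested with limma, 0 were higher and 0 lower in dnEgr at a Benjamini-Hochberg adjusted p under 0.05, and the smallest adjusted p over all 32768 probe sets was 0.99996. At an unadjusted p under 0.05 there were 230 genes, against 674 in an even distribution of p-values. Among probe sets the count was 595, against 1638, of which 341 were higher and 254 lower in dnEgr. The arrays were also scaled to the bacterial and phage hybridization spike-in RNAs instead, a choice made after the data were seen. Then 1843 probe sets were higher and 44 lower at an unadjusted p under 0.05, and 0 passed adjustment. That scaling moved the median log2 fold change of all genes from 0.0037 to 0.25. Hybridization controls cannot show a change in total RNA per cell, so this shift is not evidence of a general rise. The 3 dnEgr arrays lay entirely above or below the 3 control arrays for 720 genes, 5.34% of those tested, where chance gives 10%. On the log2 scale used here, the 95% confidence interval of the fold change lay within 2-fold in either direction for 10781 genes (79.9%). It lay within 1.5-fold for 5422 genes (40.2%). For the other genes a difference of that size was not excluded. The log2 scale understates changes of dim genes, so for dim genes within these limits a larger change in intensity was not excluded either. The intervals were not adjusted over the genes tested, and depend on the common scaling and on the brightest probe set. They thus do not exclude such a change for every gene within these limits. Of the 42 tested genes named in these results, 35 moved by more than 1.5 times in log2 fold change, or turned sign, when 1 of the 6 arrays was left out. Of the 17 with several tested probe sets, 14 did so as the mean of those probe sets.

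**Figure D1:**
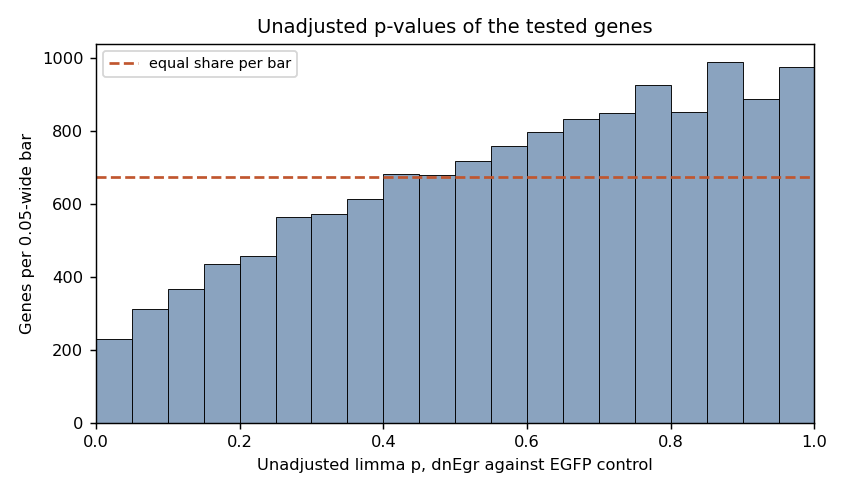
Histogram of unadjusted limma p-values of the 13485 tested genes for dnEgr against EGFP control, with the number of genes per bar on the vertical axis and a dashed line at an equal share per bar. The lowest bar holds 230 genes, below the line at 674.

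Transcripts of the Egr family itself differed between the groups by less than the spread between arrays. EGR1 had an intensity of 1246.5 ± 790 (SD, n = 3) in control and 1199.7 ± 559 (SD, n = 3) in dnEgr cells, on the brightest of its probe sets. Its log2 fold change was 0.13, with a 95% interval of −0.98 to 1.24, so the mean of logarithms and the mean intensity differed in sign. The wide interval came with 1 low array in each group: EGR1 measured 1537, 1850 and 352 on control arrays 1 to 3 and 1247, 1734 and 618 on dnEgr arrays 1 to 3. The other EGR1 probe sets gave log2 fold changes of 0.31 and −0.32. The log2 fold change ranged from −0.61 without control array 3 to 0.57 without control array 2, was −0.19 without dnEgr array 2, and was −0.20 without both arrays numbered 3. EGR3 measured 43.7 ± 17.9 and 47.5 ± 16.2 (n = 3 each, log2 fold change 0.10, interval −0.63 to 0.82). EGR4 measured 27.7 ± 15.3 and 40.1 ± 16.9 (n = 3 each, log2 fold change 0.37, interval −0.46 to 1.20). The sources used here do not say which part of Egr the construct holds, so the EGR probe sets cannot check the group labels.

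NAB1 and NAB2 encode co-repressors that bind Egr proteins, and NAB2 is itself a known Egr target. NAB1 measured 613 ± 64.7 in control and 657 ± 3.63 in dnEgr cells (n = 3 each), a log2 fold change of 0.10 with an interval of −0.24 to 0.44. Its other tested probe sets gave −0.44 and −0.051. NAB2 measured 122 ± 4.16 and 145 ± 37.9 (n = 3 each), a log2 fold change of 0.20 with an interval of −0.31 to 0.70, while its other tested probe set gave −0.25. As a list, the 5 tested Egr and Nab genes had 5 positive and 0 negative log2 fold changes, a median of 0.13, and a camera adjusted p of 0.459. EGR2 was not analysed here.

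**Figure D2:**
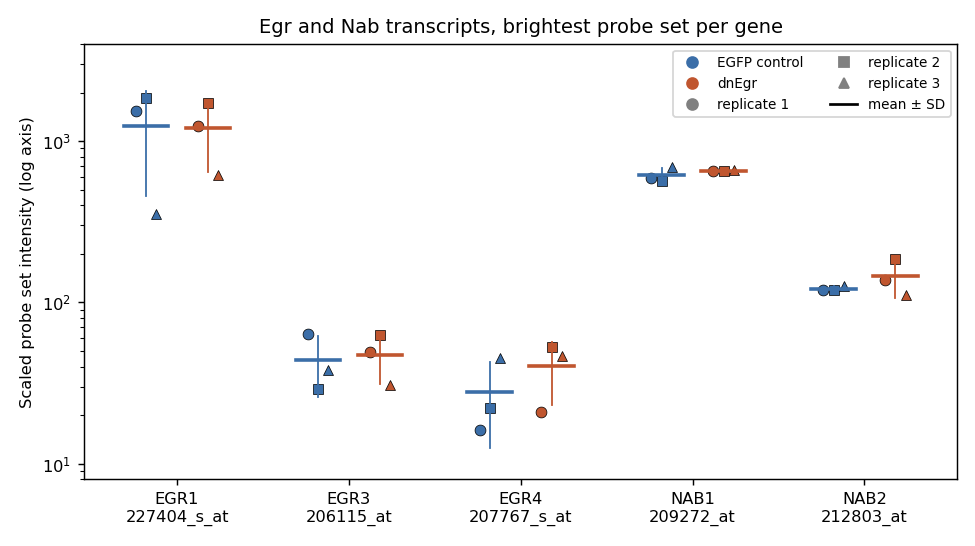
Scaled intensity on a log axis for EGR1, EGR3, EGR4, NAB1 and NAB2, with one symbol per array, blue for EGFP control and orange for dnEgr, symbol shape for the replicate number, and lines for mean ± SD (n = 3). The groups overlap for every gene shown, and EGR1 is lowest on the array numbered 3 in both groups.

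The tested genes reported as Egr targets in other cells gave no detectable shift as a group. Of 35 listed, 21 were tested, and those not tested included NGFR, SERPINE1, LDLR and TH. Of the 21, 9 had positive and 12 negative log2 fold changes, with a median of −0.013 and a camera adjusted p of 0.935. MMP14, a membrane-bound matrix metalloprotease, measured 74.0 ± 3.89 in control and 44.6 ± 19.1 in dnEgr cells (n = 3 each), and all 3 dnEgr values lay below all 3 control values. Its log2 fold change was −0.61, with an interval of −1.25 to 0.021. FLT1, a receptor for vascular endothelial growth factor, had the opposite sign, with 35.6 ± 23.3 and 77.6 ± 40.8 and a log2 fold change of 0.86 (interval −0.037 to 1.76). Both genes had adjusted p-values of 1.00. No member of this or any other list passed adjustment over all probe sets, and 0 members of each list passed when adjusted over the list alone.

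The other immediate early genes, which like EGR1 respond to growth factors within minutes to hours, also gave no detectable shift as a group. Of 29 listed, 21 were tested, and those not tested included FOS, FOSB and NR4A2. Of the 21, 12 were positive and 9 negative, with a median of 0.030 and a mean of −0.032, and a camera adjusted p of 0.721. KLF10, a transcription factor gene, measured 389 ± 23.4 in control and 311 ± 68.1 in dnEgr cells, with a log2 fold change of −0.33 and an interval of −0.75 to 0.093. CSRNP1, which encodes a nuclear protein, had a log2 fold change of −0.42. Among 20 feedback regulators of MAP kinase signalling, 8 were positive and 12 negative, with a median of −0.033 and an adjusted p of 0.721. DUSP4, a MAP kinase phosphatase, measured 1823 ± 347 and 1402 ± 353, a log2 fold change of −0.39 with an interval of −0.84 to 0.063. SPRED1, an inhibitor of the Ras to MAP kinase pathway, had a log2 fold change of −0.28 on its brightest probe set, −0.084 as the mean of its probe sets and −0.098 without dnEgr array 1. The 16 tested of 30 listed delayed NGF-response genes were split evenly, 8 positive and 8 negative. They had a median of −0.0034, a mean of −0.067 and an adjusted p of 0.721. In that list PLAT, the gene of tissue plasminogen activator, had a log2 fold change of −0.70 with an interval of −1.76 to 0.36. It measured 54.5, 3.45 and 79.3 on dnEgr arrays 1 to 3, and its log2 fold change was −0.0047 without dnEgr array 2 and −1.15 without dnEgr array 3. SCG3, a secretory granule protein gene, had −0.18.

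Genes of neuronal form and identity were similarly divided. The list of 36 neurite and cytoskeleton genes had 17 positive and 19 negative log2 fold changes (median −0.0076, camera adjusted p 0.721). CDK5, a kinase of neurons, had a log2 fold change of 0.27 (interval −0.10 to 0.65), and CDK5R2, which encodes one of its activators, had 0.34 (interval −0.11 to 0.80). CDK5R1, which encodes another activator and is also on the list of reported Egr targets, had −0.29 (interval −0.70 to 0.12). Among 31 axon and dendrite guidance genes, 17 were positive and 14 negative, with a median of 0.015 and an adjusted p of 0.935 in the downward direction. PLXNA4, a semaphorin co-receptor, measured 33.3 ± 20.9 in control and 72.9 ± 28.3 in dnEgr cells, a log2 fold change of 0.91 with an interval of 0.067 to 1.76. Its value was 0.27 as the mean of its probe sets and 0.50 without control array 2. EPHA5, an ephrin receptor, measured 35.2 ± 10.7 and 11.5 ± 8.21, a log2 fold change of −0.92 with an interval of −1.77 to −0.065. For these 2 genes the groups did not overlap, but the intensities were dim and neither passed adjustment. The 24 noradrenergic and sympathetic identity genes had 14 positive and 10 negative values, a median of 0.017, a mean of −0.0048 and an adjusted p of 0.935 in the upward direction. CHRNB4, a nicotinic receptor subunit, had a log2 fold change of −0.38, and MAOA, which degrades monoamines, had 0.16.

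Neurotrophin and GDNF receptors and ligands had 6 positive and 12 negative log2 fold changes among 18 tested, with a median of −0.041 and a camera adjusted p of 0.721. NTRK3, the receptor for neurotrophin-3, had 0.38 on its brightest probe set and −0.065 as the mean of its probe sets. NRTN, the gene of the GDNF-related factor neurturin, had −0.39. NTRK1, the gene of TrkA, was not analysed here, so the TrkA in the label of the cells was not checked. The 25 genes of synaptic vesicles and release had 13 positive and 12 negative values, a median of 0.0065 and an adjusted p of 0.721. STX1A, a syntaxin of the release machinery, measured 165 ± 26.6 in control and 210 ± 7.80 in dnEgr cells, a log2 fold change of 0.33 with an interval of −0.11 to 0.77. UNC13A, a vesicle priming factor, measured 141 ± 13.7 and 107 ± 16.6, a log2 fold change of −0.35 with an interval of −0.83 to 0.13.

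**Figure D3:**
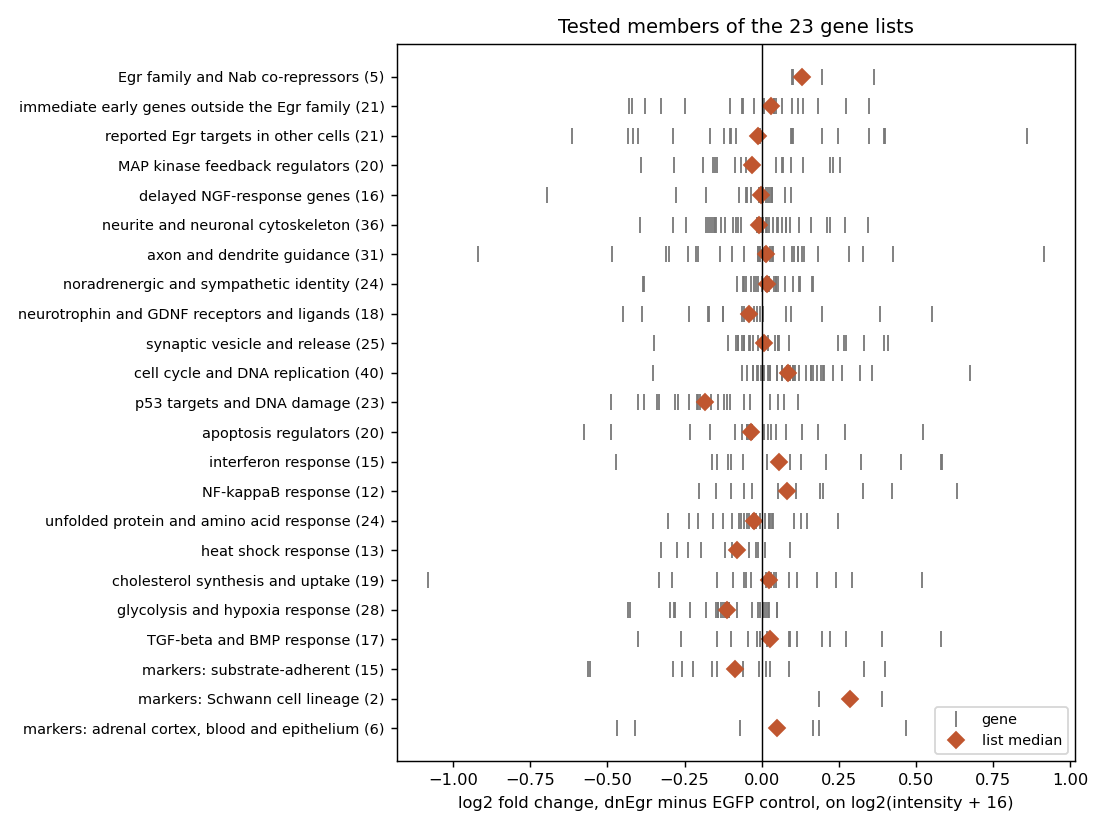
Log2 fold change (dnEgr minus EGFP control, on log2(intensity + 16)) of every tested member of the 23 gene lists, one tick per gene, with the number tested in brackets and a diamond at the list median. The medians of the 22 lists that were tested as sets lie between −0.18 (p53 targets) and 0.13 (Egr and Nab genes).

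Of all the lists, the targets of p53, the transcription factor of the DNA damage response, lay farthest below the other genes. Of 23 tested, 4 had positive and 19 negative log2 fold changes, with a median of −0.18 and a camera adjusted p of 0.166 (adjusted p = 0.958 with an estimated correlation). BAX, a promoter of apoptosis, measured 313 ± 100.2 in control and 219 ± 69.0 in dnEgr cells, a log2 fold change of −0.49 with an interval of −1.06 to 0.089. TNFRSF10B, a death receptor gene, had −0.27 on its brightest probe set, −0.057 as the mean of its probe sets and −0.11 without control array 2. PLK3, a stress-responsive kinase gene, had −0.38, which became −0.099 without dnEgr array 3 and −0.81 without dnEgr array 1. The p53 list passed the threshold with some settings and not with others. Its adjusted p was 0.0401 with a pseudocount of 64 and 0.0383 with the filter at the 60th percentile. It was 7.56e-05 without control array 1, 0.0350 without control array 3 and 1.79e-06 without dnEgr array 1. With an estimated correlation the adjusted p was 0.943 and 0.921 under these 2 settings, and 0.658, 0.908 and 0.894 without those arrays. Without control array 2 the direction turned, at an adjusted p of 0.985.

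Glycolysis and hypoxia genes had 7 positive and 21 negative log2 fold changes among 28 tested, with a median of −0.11 and a camera adjusted p of 0.237. PFKFB3, a regulator of glycolysis, had a log2 fold change of −0.43, VEGFA, a vascular growth factor gene, also −0.43, and P4HA1, a collagen prolyl hydroxylase gene, −0.29. The 40 cell cycle and DNA replication genes had 32 positive and 8 negative values, with a median of 0.087 and an adjusted p of 0.459. CCND2, a cyclin gene, was dim, with 18.4 ± 20.6 in control and 34.4 ± 14.6 in dnEgr cells, and its groups overlapped. Its log2 fold change was 0.68, with an interval of −0.31 to 1.66. CCNE1, another cyclin gene, had 0.36. CDK1, the mitotic kinase gene, had −0.35 on its brightest probe set and 0.11 as the mean of its probe sets. The glycolysis list passed without control array 3 (3.87e-05) or dnEgr array 1 (0.00185), and the cell cycle list without the same arrays (2.58e-06 and 2.27e-04). With an estimated correlation the adjusted p of both lists was 0.908 without control array 3 and 0.894 without dnEgr array 1. In both groups 10 of the 40 cell cycle genes were higher and 5 of the 28 glycolysis genes lower on the array numbered 3, among genes called by a limma F test across replicate numbers. Both lists turned direction without control array 2 or dnEgr array 3.

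Stress and defence lists also gave no call. The 13 heat shock genes had 2 positive and 11 negative log2 fold changes, a median of −0.079 and a camera adjusted p of 0.436, which became 0.0327 without control array 1 (adjusted p = 0.658 with an estimated correlation). DNAJB4, a chaperone gene, had −0.27. The 24 genes of the unfolded protein and amino acid response had 10 positive and 14 negative values, a median of −0.024 and an adjusted p of 0.721, and SDF2L1, an endoplasmic reticulum protein gene, had −0.30. Of 37 listed interferon response genes, which viral infection can switch on, 15 were tested, and those not tested included IFIT1, MX1 and STAT1. The 15 had 9 positive and 6 negative values, a median of 0.057 and an adjusted p of 0.452. ISG15, an interferon-induced ubiquitin-like protein gene, measured 36.2 ± 10.3 in control and 61.8 ± 12.0 in dnEgr cells, a log2 fold change of 0.58 with an interval of −0.059 to 1.23. NF-kappaB response genes had 7 positive and 5 negative values among 12, a median of 0.082 and an adjusted p of 0.459. TRAF1, a signalling adaptor gene, was dim, with 16.3 ± 14.5 in control and 30.8 ± 7.53 in dnEgr cells, and its groups overlapped. Its log2 fold change was 0.63, with an interval of −0.31 to 1.57. The 20 apoptosis regulators had 9 positive and 11 negative values, a median of −0.034 and an adjusted p of 0.829, with BAX again first by p. Cholesterol synthesis and uptake genes had 11 positive and 8 negative values among 19, a median of 0.024, a mean of −0.026 and an adjusted p of 0.935. MVD, an enzyme of the mevalonate pathway, measured 86.0 ± 58.6 and 34.3 ± 33.6, a log2 fold change of −1.08 with an interval of −2.12 to −0.041. The 17 TGF-beta and BMP response genes had 10 positive and 7 negative values, a median of 0.028 and an adjusted p of 0.721, and LTBP2, which encodes a TGF-beta binding protein, had 0.58 (interval −0.013 to 1.17).

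Lists of markers of other cell types gave no call between the groups. For substrate-adherent, mesenchymal neuroblastoma cells, a cell form that SH-SY5Y cultures can hold, 5 of 15 tested markers had positive and 10 negative log2 fold changes, with a median of −0.088 and a camera adjusted p of 0.459. NT5E, a surface marker of such cells, measured 38.1 ± 12.4 in control and 20.5 ± 6.61 in dnEgr cells, a log2 fold change of −0.56 with an interval of −1.32 to 0.20. Markers of adrenal cortex, blood and epithelium had 3 positive and 3 negative values among 6 tested, a median of 0.049, a mean of −0.022 and an adjusted p of 0.935. KRT18, an epithelial keratin gene, had 0.47. Of 12 Schwann cell lineage markers 2 were tested, both with positive values, too few for a list test. The others lay under the filter or had no probe set with that symbol alone. ERBB3, a neuregulin receptor gene, had 0.39. With an estimated correlation between genes, every one of the 22 lists had a camera adjusted p of 0.958.

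RNA quality, read from the 3′ to 5′ difference of 2 control transcripts, differed by less than the spread between arrays could distinguish. The log2 difference for ACTB was 0.584 ± 0.287 in control and 0.576 ± 0.0586 in dnEgr arrays (n = 3 each; exact permutation p = 1, two-sided). For GAPDH it was 0.155 ± 0.0255 and 0.203 ± 0.0870 (n = 3 each; exact permutation p = 0.5, two-sided). The 5′ control probe set of 18S ribosomal RNA measured 8821, 9504 and 481 on control arrays 1 to 3 and 5658, 1949 and 2657 on dnEgr arrays 1 to 3. Its log2 intensity was 11.76 ± 2.43 and 11.60 ± 0.787 (n = 3 each; exact permutation p = 1, two-sided). With 3 arrays against 3 the smallest possible p is 0.1. The bacterial and phage hybridization spike-in probe sets had a mean log2 intensity of 11.35 in control and 11.10 in dnEgr arrays (exact permutation p = 0.2, two-sided, n = 3 each).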

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

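Scaling to the spike-in RNAs and leaving out both arrays numbered 3, and the weighing of the blocked count against an even distribution, were chosen only after the data were seen. The count of probe sets past the limma threshold was 0 under all 19 alternatives, the fold of at least 1.5 included, and the count of genes was 0 wherever it was computed. At an unadjusted p under 0.05 the 595 of 32768 probe sets became 1635 of 54613 without a filter. With the filter at the 60th percentile they became 192, with fewer probe sets tested. These counts thus differ partly through the number tested. The 595 became 959 without a trend, 1887 with spike-in scaling, 933 without control array 3 and 969 without both arrays numbered 3. The 42 tested genes named in the results never passed the threshold (smallest adjusted p 0.687), and apart from spike-in scaling 718 of 732 recomputed fold changes kept their sign, with 32 genes keeping it throughout. Their size was less stable: 35 moved by more than 1.5 times or turned sign with 1 array left out, and 14 of the 17 with several tested probe sets did so as the mean of the probe sets. Of 438 recomputed list tests apart from spike-in scaling 10 passed and 55 turned direction. The 8 list calls made with an array left out had adjusted p-values of 0.658 to 0.908 with an estimated correlation. Camera with an estimated correlation was not tried on the simulated data. Its power is thus unknown, and these values do not decide whether a list moved. The causes of the changes between settings were not tested. How far dim intensities stood above background is unknown, which limits all dim genes.

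The shared replicate numbers did not pair the arrays for all 3 numbers. Deviations from the group mean correlated at 0.0529, 0.0844 and 0.310 for numbers 1, 2 and 3, across probe sets. The arrays numbered 3 matched each other best, but control array 2 matched dnEgr array 1 best, at 0.238. In all, 4 of 6 arrays correlated best with their own number, a hint from the data. The RNA numbers in the sample titles run consecutively, control then dnEgr, through replicate numbers 1, 2 and 3. That order also hints at pairs by number, though the labels do not say what the number marks. By the correlations, a block by number may still mismatch the arrays numbered 1 and 2. With the replicate number as a block, 0 probe sets, 0 genes and 0 lists passed. The count at an unadjusted p under 0.05 was then 904, still under the 1638.4 that an even distribution gives. A wider spread within groups from differences between replicate numbers may therefore account for part of the shortage but was not shown to account for it. With the group labels swapped within replicate numbers in the same blocked fit the counts were 1536 to 2161, which also carry other differences between the arrays, so this stays open. The guidance list (adjusted p 0.988) and the noradrenergic list (0.977) turned direction with the block.

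The number of lists past the threshold was 1 with a pseudocount of 64, with the filter at the 60th percentile and with spike-in scaling, each time the p53 list. With an estimated correlation the camera adjusted p of that list was 0.943, 0.921 and 0.968 under these settings, in that order. Among lists that turned direction, the adjusted p was 0.951 for guidance with a pseudocount of 64. Without a filter it was 0.999 for delayed NGF-response genes and 0.924 for interferon. With the filter at the 60th percentile it was 0.848 for immediate early genes, Egr targets and cholesterol, 0.834 for guidance and 0.918 for NF-kappaB. With array weights it was 0.998 for Egr targets and noradrenergic genes. With the mean of a gene's probe sets it was 0.980 for guidance, synaptic and apoptosis genes and 0.991 for adrenal, blood and epithelial markers, and the log2 fold change became −0.13 for NAB1, −0.025 for NAB2, −0.065 for NTRK3 and 0.11 for CDK1. With fry it was 0.979 for cholesterol and for adrenal, blood and epithelial markers. With spike-in scaling it was 0.873 for cell cycle, and SCG3 became 0.066. These turns and the p53 call with this scaling say nothing about the genes or lists, because it raises every log2 fold change by the same amount, and that amount alone gave the cell cycle turn (0.952) and the p53 call (0.00558). Without both arrays numbered 3 it was 0.942 for Egr targets, 0.615 for neurite genes, 0.910 for guidance and TGF-beta, 0.574 for cholesterol and 0.911 for adrenal, blood and epithelial markers, and EGR1 became −0.20.

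Leaving out each array in turn gave 0 to 3 lists past the threshold. Adjusted p ranged from 1.79e-06 to 0.985 for p53 targets, 2.58e-06 to 0.919 for cell cycle, 3.87e-05 to 0.997 for glycolysis, 0.0734 to 0.997 for unfolded protein, 0.0788 to 0.942 for cholesterol, 0.207 to 0.953 for synaptic genes, 0.282 to 0.997 for TGF-beta, and 0.301 to 0.997 for apoptosis and for neurite genes. It ranged from 0.393 to 0.997 for neurotrophin genes, 0.426 to 0.997 for immediate early genes, 0.454 to 0.997 for Egr targets, 0.454 to 0.953 for noradrenergic genes, 0.671 to 0.997 for guidance and 0.862 to 0.997 for adrenal, blood and epithelial markers. Log2 fold changes ranged from −0.61 to 0.57 for EGR1, −0.084 to 0.33 for EGR3, −0.027 to 0.29 for MAOA, −0.034 to 0.79 for CCNE1, −0.64 to 0.0077 for CDK1, −0.73 to 0.043 for PFKFB3 and −0.72 to 0.054 for VEGFA. The ACTB 3′ to 5′ difference between groups ranged from −0.123 to 0.153.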

Other observations

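The comparison across replicate numbers, the list tests on it, the test of RNA degradation and the splits of the arrays were chosen only after the data were seen. In both groups the arrays numbered 3 stood apart from those numbered 1 and 2. In a limma fit with group and replicate number, an F test across the 3 numbers called 140 genes (286 probe sets) at an adjusted p under 0.05. Data simulated without such a difference, with probe sets drawn independently, gave at most 7 probe sets. Real genes are not independent, so that figure is no chance level for the 286. Matching control array 1 with dnEgr array 2 and control array 2 with dnEgr array 1, with the arrays numbered 3 still together, gave 1041 probe sets, and the matchings that parted the arrays numbered 3 gave 0. These counts thus do not show that the labelled numbers mark a shared origin of the arrays numbered 1 and 2. The order of the RNA numbers in the sample titles hints at pairs by number. Both arrays numbered 3 lay beyond the other arrays of their own group for 139 of these genes, 67 lower and 72 higher, against 29 for number 1 and 33 for number 2. SLC18A1, a vesicular monoamine transporter, measured 1035, 807 and 184 on control arrays 1 to 3 and 822, 590 and 136 on dnEgr arrays 1 to 3 (F test adjusted p 6.15e-05). EGR1 was among the lower genes (adjusted p 0.00168), with the values given for each array in the results. TXNIP, an inhibitor of thioredoxin, went the other way, with 111, 90.1 and 547 in control and 85.1, 43.2 and 531 in dnEgr (adjusted p 2.12e-04). CXCR4, a chemokine receptor, was lower on the arrays numbered 3 and INHBA, a subunit of activin, was higher.

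The genes that differed included 10 of 40 tested cell cycle genes, all higher on both arrays numbered 3, against 1.04% of all genes (Fisher's exact test, two-sided, adjusted p 1.50e-10 over 22 lists; genes are not independent, so this p is too small). BUB1B, a mitotic checkpoint kinase, measured 649, 412 and 1476 on control arrays 1 to 3 and 510, 745 and 1561 on dnEgr arrays 1 to 3. PCNA, a replication clamp, and CCNB1, a mitotic cyclin, were also among the 10. Glycolysis and hypoxia genes gave 5 of 28, all lower on both arrays numbered 3 (adjusted p 1.00e-04). These were VEGFA, ALDOA, ALDOC, ADM and BNIP3, and VEGFA measured 3225, 3050 and 1741 in control and 2522, 2841 and 962 in dnEgr. Noradrenergic genes gave 3 of 24 (adjusted p 0.0139), of which SLC18A1 and DDC, the enzyme that makes dopamine, were lower and RET, a GDNF receptor subunit, was higher. No other list passed, including immediate early genes with 1 of 21 and Egr targets with 2 of 21 (adjusted p 0.0869). SLC18A1, TXNIP, CXCR4 and INHBA, and the list members named here, were chosen after their values were seen.

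Of explanations for the arrays numbered 3, array scaling is argued against by quantile normalization, after which 231 probe sets were called against 286 before. Noise of dim probe sets is argued against by the probe sets above the 75th percentile of mean log2 intensity, of which 2.09% differed against 0.873% of all tested probe sets. A difference in RNA degradation stays open: the ACTB 3′ to 5′ log2 difference averaged 0.459 on them and 0.640 ± 0.188 (SD) on the 4 other arrays, and that of GAPDH 0.181 and 0.178 ± 0.0811, neither beyond the spread. A difference in culture, such as density or growth state, or in the day of the experiment, also stays open, and no biological explanation was tested because the design names none.

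The absence of calls between dnEgr and control was weighed against the number of arrays. It was not weighed against the strength of the block by dnEgr, which was not checked here. In simulated data with the real spread, 33% of probe sets changed 2-fold were called but 75.9% of those changed 3-fold. These folds are on the log2 scale of the fit, which understates changes of dim probe sets. Simulated unchanged groups gave 1552 to 1738 probe sets at an unadjusted p under 0.05, against 595 in the real data. The simulation thus did not resemble the data in this count, and its rates do not show how many real changes would have been called. Changes of 2-fold in a limited number of genes may have been missed, and whether 3-fold changes would have given calls stays open. The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 0 probe sets past the threshold, a count that any split equals or exceeds, so the splits say nothing about chance here. The highest other, 28, was for control arrays 1 and 2 with dnEgr array 1 against the rest, which points to a structure of the samples other than the groups. The 18S ribosomal RNA control was higher on exactly these 3 arrays (8821, 9504 and 5658) than on the rest (481, 1949 and 2657), a match noticed after the data were seen. A difference in RNA preparation along this split therefore stays open. The 595 probe sets at an unadjusted p under 0.05 were the fewest of the 10 splits. The split with 28 past the threshold gave 4196. The highest, 4706, was for control arrays 1 and 3 with dnEgr array 3 against the rest, with 0 past the threshold. The 18S values do not follow that other split.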
